A study of Mus musculus with 4 samples.

How the data were processed

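Total RNA from 4 cultures of 3T3-L1 preadipocytes was hybridised to Agilent mouse arrays of design 028005 with the dye Cy3, 1 culture per array, per the labels and the file headers. Groups were taken from the labels: control and Lamp2a knockdown, each at day 0 and day 2, 1 array per group. The medium held 10% serum, per the labels' protocols. How the knockdown was made is not given in the sources used here. Each array was read with Agilent Feature Extraction 10.7.3.1, per the file headers, which subtracted a spatial background from every spot. Per the file headers, a multiplicative detrending followed on 3 arrays and was not applied to the knockdown day 0 array. The resulting processed signals are intensity values on a linear scale, not normalised between arrays, and were deposited as 1 file per array. In the deposited file of the control day 0 array, the intensity values are rounded to 3 significant digits, and on the other arrays they have 7. The control day 0 array comes from slide 1 and the other arrays from slide 2, so slide and group cannot be told apart in the comparisons that use that array. No spot was saturated. The background-subtracted mean of 308 negative-control spots was -12.5, -6.67, -7.49 and -9.10 on the control day 0, knockdown day 0, control day 2 and knockdown day 2 arrays.

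Each array held 59305 non-control spots of 55681 probes. Control spots were left out, as were spots that the software marked as non-uniform (63, 7, 1 and 0 on the arrays in the order above) or as population outliers (199, 171, 167 and 156). The log2 of the processed signal minus the 75th percentile of the array is the level of a spot, and repeat spots of a probe were averaged. Probes were named through their unversioned RefSeq accession in a gene table of assembly GRCm38.p6, used for names only. In this way 27656 probes matched 20972 genes, and 28025 probes did not match, of which 16194 are named by chromosome position. No coordinates are given because the array's own positions refer to another build. Of 5554 genes with more than 1 probe, the probe with the highest mean level over the 4 arrays stands for the gene. After outlier spots were left out, 20956 genes remained.

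A gene was compared where it was well above background, by the software's mark, on at least 1 of the 2 arrays. Where it was so on only 1, the other side was set to the higher of its own level and the lowest level well above background on that array, so that the difference is a bound, written as at least N-fold. A bound that read higher on the side not well above background was set to 0, and such zeros enter the list medians. Comparisons were knockdown against control at each day, day 2 against day 0 in each kind of cell, and the difference between the knockdown log2 ratios of the days over genes well above background on all 4 arrays. With 1 array per group there is no replicate spread to test against, no test was run, and a fixed size of 2-fold calls a gene. The design, gene lists, rule for named genes and the other settings to try were fixed before the data were examined. For each of 38 gene lists, the median log2 ratio was set against 10000 random lists of the same size, drawn within 20 classes of signal, and its percentile describes these arrays only. A list outside the percentiles 2.5 to 97.5 is described as outside the central 95%.

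The rule for named genes took, per comparison and direction, the 8 largest differences measured on all arrays of the comparison and the 3 largest bounds. For the 8 largest, other probes of the gene had to go the same way where they were well above background on those arrays. The rule also took up to 2 members of each gene list past 2-fold. Always taken were 14 genes: Lamp2, Pparg, Cebpa, Cebpb, Cebpd, Fabp4, Adipoq, Dlk1, Myc, Smad3, Tgfb1, Ccnd1, Mki67 and Cdkn1a. Not every gene the rule took is printed.

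The 11394 bright genes, chosen after the data were seen, are those whose mean level exceeded the 95th percentile of 1072 olfactory receptor genes. The spot SD comes from 399 probes printed 10 times. Other settings, chosen before the data were examined, were normexp background correction with an offset of 50, quantile and cyclic loess normalization (3 iterations), scaling to the 75th percentile of probes well above background on all arrays, 2 other filters on dim probes, the median of all probes of a gene, outlier spots kept, and a 1.5-fold size. The files hold no mean signal per spot, so normexp was run on the median signal and the median local background. Added afterwards were bright genes only and the background-subtracted signal without detrending. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used. The calling rule was tested on simulated data: for knockdown against control at day 2, 20956 genes were simulated with the spot error of the arrays, and all of 100 bright genes made 3-fold higher and all of 100 made 4-fold lower were called (100.0% each), with 8 calls among unchanged genes. Of 100 simulated lists of unchanged genes, 6 fell outside the central 95%. The simulation held spot error and no spread between cultures, so it checks the rule and not how many real calls would recur in other cultures. Comparisons that use the control day 0 array were not simulated.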

Results

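Gene expression was measured in 3T3-L1 cells, a mouse preadipocyte line that turns into fat cells when exposed to adipogenic hormones. RNA came from control preadipocytes and from preadipocytes in which lamp2a was knocked down, and each was sampled at confluence (day 0) and at day 2 of adipogenic induction with 160 nM insulin, 250 nM dexamethasone and 0.5 mM isobutylmethylxanthine. LAMP2A is the splice form of the lysosomal membrane protein LAMP2 that acts as receptor in chaperone-mediated autophagy, the uptake of single cytosolic proteins into lysosomes for degradation. Each of the 4 groups had 1 array, so no difference has a replicate check and no p-value is given. A gene is called higher or lower where its normalised signal differed by at least 2-fold between 2 arrays. The number of arrays limits the precision, and repeat spots measure only the error within arrays: probes printed 10 times gave a spot SD of the log2 ratio of 0.06 to 0.07 for bright genes and 0.31 to 0.41 for dim genes.

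Dim genes read lower on the control day 0 array than on the other arrays. Of 59305 spots, 67.4% were well above background on the control day 0 array, 88.6% on the knockdown day 0 array, 84.2% on the control day 2 array and 78.7% on the knockdown day 2 array. The 1072 olfactory receptor genes, which fibroblasts are not known to express, had median signals of 11.2, 39.8, 28.7 and 23.6 on these arrays. In the knockdown to control comparison at day 0, the median log2 ratio was 0.98 in the second lowest of 5 brightness classes and -0.06 in the brightest class. The control day 0 array was also alone on its slide, and the other 3 arrays shared another slide. The knockdown comparison at day 0, the control time course and the difference between the knockdown log2 ratios use that array, so they also cross slides. Counts are therefore given for all compared genes and for the 11394 bright genes, those whose mean level exceeded the 95th percentile of the olfactory receptor genes. Dim genes are named as such.

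**Figure D1:**
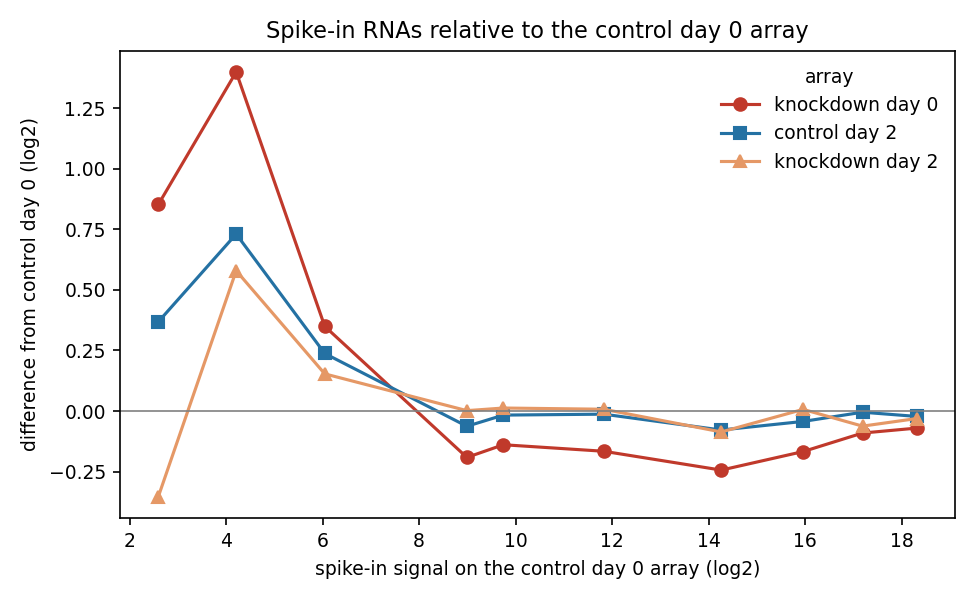
Log2 difference from the control day 0 array (vertical axis) of 10 spike-in RNAs, synthetic transcripts not made by the cells, against their log2 signal on that array (horizontal axis), with 1 line for each other array; each point is the median of 35 spots, scaling left out. On the knockdown day 0 array the 3 dimmest spike-ins read 0.35 to 1.40 higher and the 7 brighter ones between -0.24 and -0.07. The same 3 read 0.24 to 0.73 higher on the control day 2 array, and on the knockdown day 2 array they went both ways, at -0.35, 0.58 and 0.15.

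The targeted gene, Lamp2, is covered by 2 probes that gave different readings. The probe annotated to transcript NM_001017959 was 4.13-fold lower in knockdown than in control cells at day 0 and 3.51-fold lower at day 2. The probe annotated to NM_010685 was 1.29-fold lower at day 0 and 1.08-fold lower at day 2. Processed signals of the first probe were 31300 and 7931 at day 0 and 14120 and 3575 at day 2, in control and knockdown cells. The files do not say which splice form each probe reads.

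In control cells, glucocorticoid-responsive genes, early adipogenic regulators and fat-cell genes were higher at day 2 than at day 0, and interferon-stimulated genes were lower. No culture without the hormones was measured at day 2, so their effect and that of time cannot be told apart in either kind of cell. Cell-cycle lists had medians below 0 with few members past 2-fold. Of 18 glucocorticoid-responsive genes, 14 were at least 2-fold higher and 1, the dim gene Hif3a, whose probes went both ways, was 2.38-fold lower at its brightest probe. The list had a median log2 ratio of 2.60. Cebpd and Cebpb, the first transcription factors of the adipogenic cascade, were 5.06-fold and 3.48-fold higher, Pparg and Cebpa, which drive terminal differentiation, 2.49-fold and 2.27-fold higher, and Klf5 7.27-fold higher. The fatty acid carrier Fabp4 was 10.9-fold higher, Agt, which encodes angiotensinogen, 11.0-fold higher, and the dim genes Plin1, of the lipid droplet coat, and Adipoq, which encodes adiponectin, 13.8-fold and at least 4.58-fold higher. All 23 interferon-stimulated genes compared were at least 2-fold lower, with a median log2 ratio of -3.18.

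Mature adipocyte markers as a list had 17 of 24 members at least 2-fold higher and 1, the lipid droplet gene Plin4, 2.03-fold lower. Their median log2 ratio was 1.58 over all members and 1.04 over the bright ones. Pro-adipogenic transcription factors had 10 of 19 members higher and Zfp467 2.34-fold lower at its brightest probe, though its median over all probes was 0.27 on the log2 scale. The acute-phase gene Lcn2 was 47.6-fold higher and Saa3 22.8-fold higher. Among cAMP-responsive genes, 8 of 17 were higher, with Rgs2 at 9.84-fold and the phosphodiesterase gene Pde4b at 9.17-fold, and the stress-induced factor Atf3 was 4.79-fold lower. Gata2 and Gata3, which restrain preadipocytes from differentiating, were 6.33-fold and 5.67-fold lower, and Dlk1, a further inhibitor of adipogenesis, differed by 1.35-fold. In the cell cycle, Ccnd1 was 2.95-fold lower and Foxm1 2.54-fold lower, while Top2a was 3.22-fold and Pcna 2.15-fold higher, the latter at a log2 ratio of 0.91 after quantile normalization. The median log2 ratios of the G2/M and S-phase lists were -0.66 and -0.48, with 4 of 25 and 2 of 33 members lower by 2-fold and 1 of each list higher. The growth regulator Myc was 3.07-fold higher and Mki67, a proliferation marker, 1.77-fold lower.

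Matrix and contractile genes also differed between the days in control cells. Timp3, an inhibitor of matrix proteases, was 22.7-fold lower, Sfrp2, a secreted Wnt modulator, 13.3-fold lower, Ccn4 6.57-fold lower and Thbs1 7.12-fold lower, whereas the basement membrane collagen genes Col4a1 and Col4a2 were 3.41-fold and 2.59-fold higher. The extracellular matrix list had 6 of 29 members lower and 2 higher, with a median of -0.25. Actg2 and Myl9 were 15.0-fold and 8.33-fold lower, and their smooth muscle list had 4 of 10 members lower and 1 higher. Lysosomal proteins had a median log2 ratio of -0.48, with 5 of 31 members lower, Ctsk by 4.31-fold, and 1 higher, and cytosolic ribosomal proteins one of 0.51, or 0.06 after quantile normalization, with no member past 2-fold. Among bright genes, the largest differences measured on both arrays included the eosinophil-associated ribonuclease genes Ear2, Rnase2a, Ear10 and Ear6 and the acute-phase genes Orm2 and Orm3, at 1492-fold, 376-fold, 268-fold, 101-fold, 87.7-fold and 81.2-fold higher. Lower ones were Ifit3, Ifit3b, Gpr176 and Oas2, at 85.0-fold, 83.9-fold, 51.9-fold and 48.9-fold. The size of the Ear2 and Ear10 differences rests on low signals of the control day 0 array and depends on the processing. With normexp their log2 ratios were 9.01 and 6.88, against 10.54 and 8.07 in the main setting. The Ear and Rnase2a genes, the Orm genes and the Ifit3 pair are near-identical copies, and which member each probe reads is uncertain. Pip, Ear1 and Cxcl13 were not well above background at day 0 and were at least 1957-fold, 1310-fold and 477-fold higher at day 2 in the main setting. For Pip the bound as a log2 ratio was 10.93 there, 10.06 after quantile normalization and 9.04 with normexp.

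In total, 3712 of 18657 compared genes were at least 2-fold higher in control cells at day 2 and 1520 were lower. Among bright genes the numbers were 866 and 883. The split depended on the scaling: 71.0% of the called genes were higher in the main setting, 37.2% after quantile normalization and 30.1% after cyclic loess. Of the 38 gene lists fixed before the data were examined, 7 had a median above and 8 below the central 95% of 10000 random lists matched on signal.

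In knockdown cells, glucocorticoid-responsive genes were also higher at day 2, but Pparg and Cebpa differed little from day 0 and cell-cycle genes were far lower. Cebpd was 7.31-fold and Cebpb 5.16-fold higher at day 2 than at day 0, while Pparg was 1.08-fold lower, Cebpa 1.27-fold higher and the dim gene Adipoq 1.41-fold higher. Fabp4 was 12.6-fold higher. Of 26 genes of G2 and mitosis, 24 were at least 2-fold lower, and of 33 S-phase genes 20 were, with median log2 ratios of -1.65 and -1.29. The mitotic genes Nusap1 and Foxm1 were 5.78-fold and 5.57-fold lower, the nucleotide enzyme gene Tk1 6.58-fold lower, Ccnd1 8.16-fold lower and Mki67 4.74-fold lower.

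The glucocorticoid-responsive list had 14 of 18 members higher and the dim gene Hif3a 3.15-fold lower at its brightest probe, though its median over all probes was 0.175 on the log2 scale, with a median log2 ratio of 2.31. For cAMP-responsive genes 10 of 18 were higher and Egr1 was 2.36-fold lower, Rgs2 was 26.5-fold higher and the phosphodiesterase gene Pde4d had a log2 ratio of 4.64. Mature adipocyte markers had 5 of 24 members higher and 2 lower, Plin4 at 10.6-fold and Fabp5 at 6.33-fold, with a median of 0.48 over all members and 0.83 over the bright ones. Of 19 pro-adipogenic transcription factors, 8 were higher and 3 lower. Ppargc1a, a coactivator of mitochondrial genes, was 5.27-fold higher and Klf4 2.41-fold lower. Interferon-stimulated genes were lower in 20 of 23 cases, with a median of -2.78. Ifit3 was 310.2-fold lower and Oas1a 56.9-fold lower. Cholesterol synthesis genes had a median of -0.77, with 8 of 24 members lower, among them Fdps at 3.29-fold and Insig1 at 2.21-fold, and Hsd17b7 2.66-fold higher. The growth factor gene Igf1 was 15.1-fold lower, Vegfa 7.05-fold higher and Il6 9.29-fold higher. The Notch target Hes1 was 4.87-fold higher, Id2 and Id1 6.05-fold and 5.68-fold higher, Pdgfrb 3.94-fold lower and Odc1 3.72-fold lower. Of the contractile genes, Myl9 and Acta2 were 83.9-fold and 28.2-fold lower.

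Among bright genes, the largest differences on both knockdown arrays included Fam110c, Ear1, Ear2, Orm3, Cxcl13 and Orm2, at 108-fold, 103-fold, 92.6-fold, 87.1-fold, 86.0-fold and 40.4-fold higher, and Ifit3b, the formin gene Fhod3 and the protease gene Htra1, at 108-fold, 58.8-fold and 48.7-fold lower. Gpr176 and Itgbl1 were at least 76.3-fold and 125-fold lower. In total, 959 of 19198 compared genes were at least 2-fold higher and 1716 lower, or 703 and 1051 among bright genes. Both arrays lay on the same slide. Of the 38 lists, 8 had a median above and 9 below the central 95% of random lists.

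At day 0, before induction, knockdown cells differed from control cells in matrix, contractile, interferon-stimulated, cell-cycle and glycolysis genes. Of 23 interferon-stimulated genes, 16 were at least 2-fold lower in knockdown cells and none higher, with a median log2 ratio of -1.43. The antiviral synthetase gene Oas1a was 17.9-fold and the ISG15 protease gene Usp18 5.37-fold lower. The G2/M and S-phase lists had medians of 0.82 and 0.58, with 8 of 26 and 4 of 33 members at least 2-fold higher and no member of either lower by that size. Mki67 was 2.36-fold and Ccna2, a cyclin of S phase and mitosis, 2.49-fold higher. Glycolysis genes had a median of 0.49 with 6 of 21 members higher, Aldoc at 2.92-fold and the lactate transporter gene Slc16a3 at 2.18-fold.

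Among adipogenic regulators at day 0, Pparg was 1.01-fold higher, Cebpb 1.22-fold higher, Cebpd 1.37-fold lower and Dlk1 1.04-fold higher. Of 19 pro-adipogenic transcription factors, Cebpa and Zfp467 were 2.00-fold and 2.57-fold lower, Ebf2 and Klf5 2.38-fold and 2.13-fold higher, and no other passed 2-fold. Fabp4 was 5.33-fold higher in knockdown cells. Hes1 was 4.06-fold and Thy1, a fibroblast surface marker, 2.98-fold lower. Lysosomal proteins were modestly lower as a list, with a median of -0.53, and the protease gene Ctsk was the only member past 2-fold, at 13.7-fold lower. Macroautophagy genes had a median of -0.33 with no member past 2-fold. Stress-response genes Trib3 and Ddit3 were 3.99-fold and 2.92-fold lower, and their list had a median of -0.29. Myc was 1.55-fold higher, Cdkn1a, an inhibitor of cell-cycle kinases, 1.78-fold lower and Ccnd1 1.23-fold higher.

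Timp3 was 81.7-fold lower in knockdown cells at day 0, Tgfbi, which encodes a matrix protein induced by TGF-beta, 59.3-fold, the matrix protease gene Mmp3 26.8-fold and Sfrp2 25.1-fold lower. The extracellular matrix list had a median of -0.50, with 3 of 29 members lower and 1, the dim gene Eln, 2.17-fold higher, or 0.49 on the log2 scale after quantile normalization. The sarcoglycan gene Sgcb was 59.6-fold lower, Actg2 53.1-fold, Cdo1, of cysteine breakdown, 32.6-fold, Tagln 8.82-fold and Acta1 4.29-fold lower. The smooth muscle and myofibroblast list had 5 of 10 members lower and 2 higher, the dim genes Cnn1, by 3.20-fold, and Myh11, by at least 2.16-fold. After quantile normalization these 2 had log2 ratios of 0.87 and 0, the latter a bound set to 0, and neither passed 2-fold. In the skeletal muscle list, Acta1 was the only member lower by 2-fold and 5 of 12 were higher by that size, among them the dim genes Myog, by 5.59-fold, and Ckm, by at least 4.58-fold. Higher in knockdown cells were Dynap, Aspg and Sema5a, at 19.4-fold, 18.0-fold and 14.2-fold, and, among dim genes, Blnk, Padi3, Ngef, Padi2 and Myh1, at 12.8-fold to 18.3-fold. The transforming growth factor gene Tgfb1 and its transducer Smad3 were 1.32-fold lower and 1.17-fold higher.

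Of 19270 compared genes, 3522 were at least 2-fold higher in knockdown cells at day 0 and 809 lower. Among bright genes, 641 were higher and 353 lower. As in the control time course, the split depended on the scaling, with 81.3% of called genes higher in the main setting, 45.8% after quantile normalization and 36.2% after cyclic loess. Of the 38 lists, 9 had a median above and 8 below the central 95% of random lists. The bone and cartilage list, at 1.55, lay above it with mostly dim members, and its bright members had a median of 0.04. It stayed outside in 7 of 9 other settings. The housekeeping list also lay above the central 95% at day 0, with a median of 0.20 at the 98.5 percentile, and did so in 8 of 10 other settings. A list called at day 0 with a median of that size therefore need not be one of regulated genes.

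**Figure D2:**
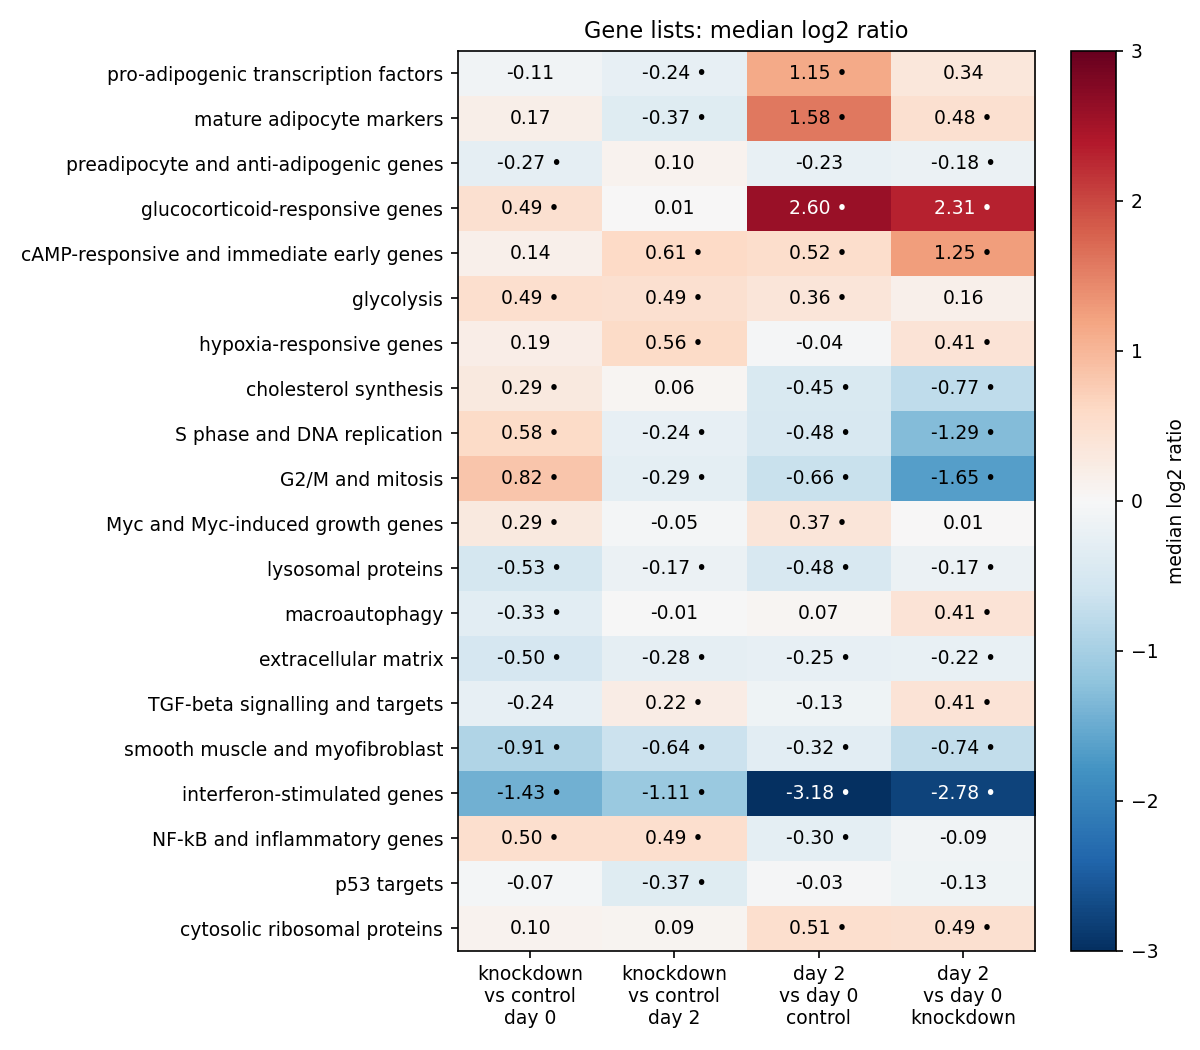
Median log2 ratio (colour, number in each cell) of 20 of the 38 gene lists in the 4 comparisons, over the genes compared; a dot marks medians outside the central 95% of 10000 random lists of the same size and signal. The G2/M list reads 0.82 for knockdown against control at day 0 and -0.29 at day 2, and the interferon list is below 0 in each comparison.

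At day 2, knockdown cells had lower levels of adipogenic regulators and fat-cell genes than control cells, together with lower interferon-stimulated genes and higher immediate early, hypoxia-responsive and glycolysis genes. Pparg was 2.67-fold, Cebpa 3.59-fold and Ebf1 2.75-fold lower in knockdown cells, and the dim gene Adipoq 3.07-fold lower. The lipid droplet gene Plin4 was 10.2-fold and Agt 4.51-fold lower, and 7 of 24 mature adipocyte markers were at least 2-fold lower, with a median log2 ratio of -0.37. The 1 marker that was higher was Fabp4, at 6.13-fold. Of the earlier regulators, Cebpb was 1.81-fold and Cebpd 1.06-fold higher.

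Pro-adipogenic transcription factors as a list had a median of -0.24, with 7 of 19 members lower and 2 higher, Ppargc1a at 12.0-fold and the dim gene Klf15 at 2.31-fold. Among preadipocyte and anti-adipogenic genes, Gata2 was 6.56-fold and Gata3 2.27-fold higher, Zfp521 2.69-fold lower and Dlk1 1.04-fold higher. Immediate early and cAMP-responsive genes had 5 of 17 members higher and none lower, with a median of 0.61, led by Pde4b at 3.60-fold and Junb at 3.50-fold. Hypoxia-responsive genes had 5 of 14 members higher and a median of 0.56, with Bhlhe40 at 2.60-fold and Bnip3 at 2.48-fold. Glycolysis genes again had a median of 0.49, with 3 of 21 members higher, Eno2 at 5.69-fold and Pfkfb3 at 2.26-fold among them. Interferon-stimulated genes were lower in 12 of 23 cases, Oas1a by 49.0-fold and Ifit3 by 9.86-fold, while Gbp2 was 2.37-fold higher, and the list's median was -1.11. The S-phase and G2/M lists had medians of -0.24 and -0.29, and of their members only Pcna, Rrm2 and Top2a passed 2-fold, at 2.52-fold, 2.31-fold and 2.66-fold lower. Ccnd1 was 2.26-fold and Mki67 1.13-fold lower.

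In the TGF-beta list at day 2, members went both ways: Tgfb2 and Smad3 were 3.83-fold and 2.02-fold higher, Tgfbi and Ltbp2 65.2-fold and 11.8-fold lower, and Tgfb1 1.19-fold higher. The list's median of 0.22 lay at the 98.0 percentile of random lists, and it stayed outside their central 95% in 6 of 10 other settings. Matrix genes were lower in 5 of 29 cases, Timp3 and Mmp3 each by 31.1-fold, and Dcn was 2.85-fold higher. Sfrp2 was 8.04-fold, Myl9 35.3-fold, Actg2 17.2-fold, Igf1 10.9-fold, Ctsk 8.03-fold and Saa3 5.80-fold lower, and the matrix phosphoprotein gene Spp1 was 10.9-fold higher. The p53 target list had a median of -0.37, with Trp53inp1 3.62-fold lower and Cdkn1a 1.18-fold lower. Lysosomal proteins had a median of -0.17, below the central 95% of random lists, with 24 of 31 members below 0 and 1 lower by 2-fold. The macroautophagy list, at -0.01, lay within the central 95%. Among bright genes, the largest differences measured on both arrays included Pip, Apod, Oas1a, Clca3a1, Clca3a2 and Cdo1, at 109.6-fold, 87.3-fold, 49.0-fold, 47.9-fold, 44.0-fold and 37.5-fold lower, and Tesc, Gdnf, Stab2, Slpi and Ramp3, at 29.8-fold, 16.5-fold, 16.1-fold, 12.6-fold and 12.2-fold higher. The Clca3a genes are near-identical copies, and which of them each probe reads is uncertain. The dim gene Ramp2 was not well above background in knockdown cells and was at least 98.7-fold lower in the main setting. As a log2 ratio its bound was -6.62 there, -6.89 after quantile normalization and -4.47 with normexp.

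Of 18561 compared genes, 537 were at least 2-fold higher in knockdown cells at day 2 and 738 lower, or 344 and 411 among bright genes. Both arrays lay on the same slide. Of the 38 lists, 6 had a median above and 11 below the central 95% of random lists. The lists of macrophage, endothelial, epithelial and skeletal muscle markers lay within it in each of the 4 comparisons. The smooth muscle and myofibroblast list lay below it in all 4, with medians of -0.91 and -0.64 for knockdown against control at days 0 and 2, and of -0.32 and -0.74 for the control and knockdown time courses.

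**Figure D3:**
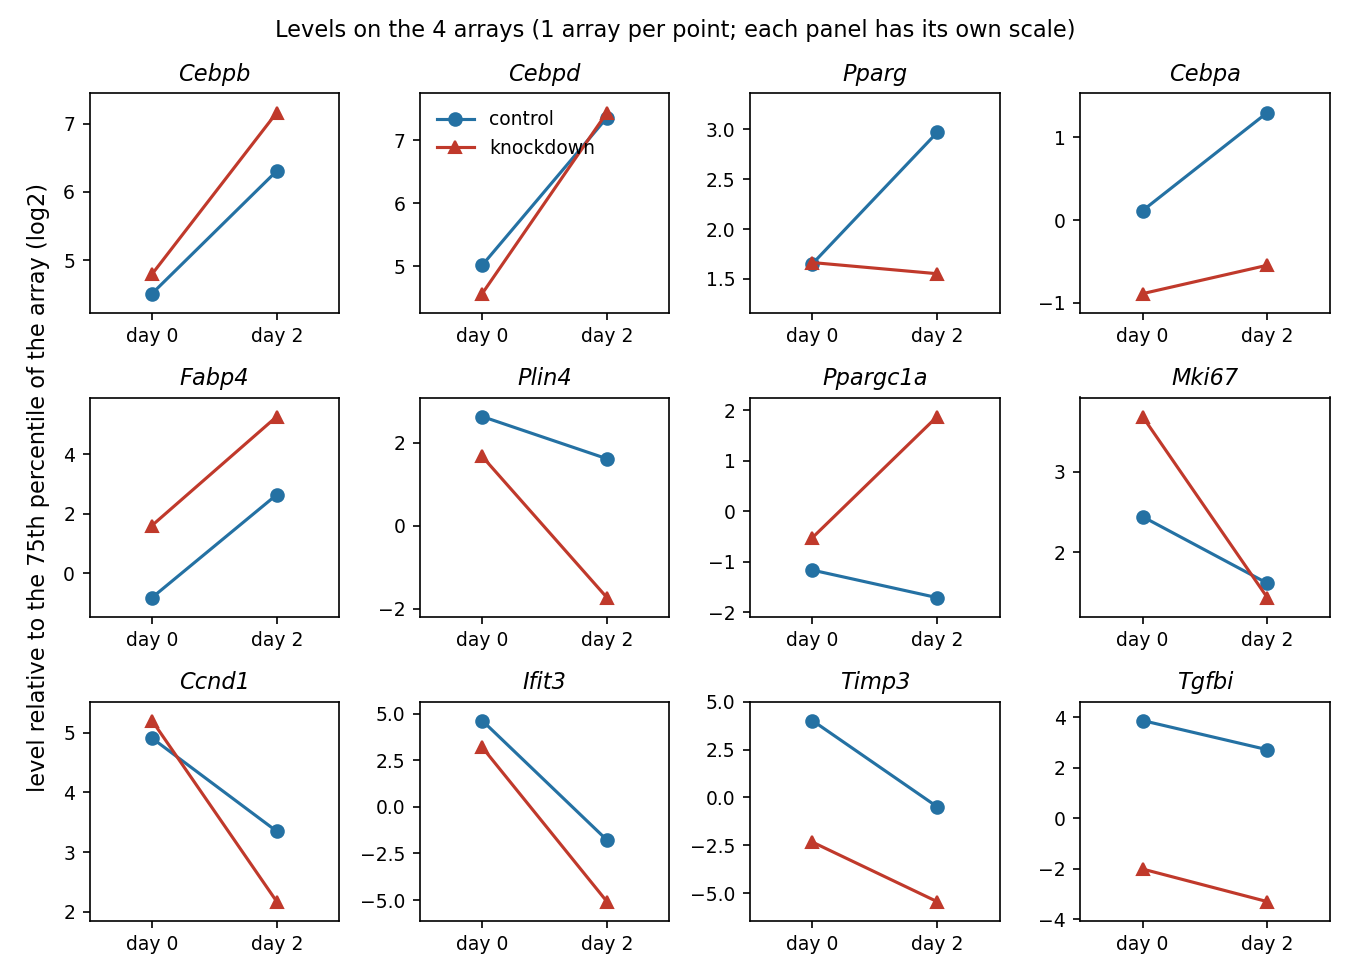
Log2 level relative to the 75th percentile of each array (vertical axis) of 12 genes on the 4 arrays, 1 panel per gene and 1 point per array, with lines joining day 0 and day 2 of control and knockdown cells. Pparg was 2.49-fold higher at day 2 in control cells and 1.08-fold lower in knockdown cells, while Cebpd was higher at day 2 in both, by 5.06-fold and 7.31-fold.

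The knockdown differences at day 0 and day 2 were compared with each other to ask which differences were present before induction and which appeared only at day 2. Of the 344 bright genes higher in knockdown cells at day 2, 31.1% were also higher at day 0, against 5.63% of bright genes in all, and independent lists would share 19.4 genes. Lower at both days were 167 bright genes, where independent lists would share 12.7. Genes on the lists of both days included Timp3, Mmp3, Tgfbi, Sfrp2, Actg2, Ctsk, Cdo1 and Oas1a, all lower, and Fabp4, higher. In opposite directions, 15 bright genes were higher at day 0 and lower at day 2, and 4 were lower and then higher. Across all genes well above background on every array, the log2 ratios of the 2 days correlated with Pearson's r = 0.36, and across bright genes with r = 0.50. Genes are not independent replicates, so r describes these arrays.

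The knockdown log2 ratio was at least 1 lower at day 2 than at day 0 for 2610 of 15465 genes and at least 1 higher for 448, or 755 and 303 among bright genes. The share of higher genes among these calls was 14.6% in the main setting, 44.7% after quantile normalization and 56.9% after cyclic loess. The difference between the ratios was -1.43 for Pparg, -0.84 for Cebpa, -1.42 for Mki67, -1.47 for Ccnd1 and -2.05 for Top2a, and it was 2.94 for Ppargc1a, 2.60 for Gata2, 1.96 for Pde4d and 0.20 for Fabp4. Of 25 genes of G2 and mitosis, 16 had a ratio at least 1 lower at day 2, as did 13 of 32 S-phase genes, with none higher. Mature adipocyte markers had 12 of 21 lower, with a median of -1.37 over all members and -0.42 over bright ones. Between control and knockdown cells, the day 2 to day 0 ratios correlated at r = 0.61 across all genes and 0.74 across bright genes. Of the bright genes, 322 were higher in both and 614 lower in both, against 53.4 and 81.4 expected of independent lists.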

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

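The difference between the days was not tested for any result here, since each group has 1 array, and the test of array response in the cell cycle and the list of growth-arrest genes were set before their results were seen. The knockdown ratio of cell-cycle genes went in opposite directions at the 2 days. The S-phase list had a median log2 ratio of 0.58 at day 0 and -0.24 at day 2, a difference of -0.82, and the G2/M list one of 0.82 and -0.29, a difference of -1.12. Of 54 bright genes of the lists, 51 were above 0 at day 0 and 43 below 0 at day 2. The prediction for a weaker low-signal response of the control day 0 array was that cyclic loess, which removes brightness-dependent differences, would end the day 0 difference. After it the bright members still had a median of 0.61, against 0.64 before. All bright genes together had a day 0 median of -0.02, so loess had little to remove among them and the test could not decide. The values show only that these members differed from bright genes as a whole. A candidate explanation is that the knockdown culture was less growth-arrested at confluence. It predicts that a list of 20 growth-arrest genes has a day 0 median below the central 95% of random lists. The median log2 ratio was 0.02, at the percentile 66.8, so this prediction was not met. Members went both ways, with 11 above 0 and 9 below, and 2 were at least 2-fold lower and 0 higher. A median near 0 over such members does not exclude a less growth-arrested culture, which stays open. The slide of the control day 0 array cannot be told apart from the day 0 comparison.

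Among named genes, these also lay past 2-fold in opposite directions at the 2 days. The log2 ratio of knockdown to control was 1.25 at day 0 and -1.38 at day 2 for Ebf2, a transcription factor of the adipocyte lineage, a difference of -2.63. For the actin regulator gene Fhod3 it was 1.65 and -1.74, a difference of -3.39. For the cytokine gene Il6 it was -1.59 and 1.24, a difference of 2.82. For Pip, not well above background in control cells at day 0, it was at least 1.19 and then -6.78, and the difference of -7.97 is a bound. The ribonuclease genes Ear2 and Ear10, near-identical copies, differed by -4.01 and -4.72. The day 0 direction of these 3 genes is uncertain: their signals were low there, with ratios of 1.17 for Ear2 and 1.43 for Ear10, and the olfactory receptor genes had a median of 1.30 between the same arrays. After quantile normalization Pip, Ear2 and Ear10 were at 0.03, 0.12 and 0.51 at day 0, and Ebf2 at 0.94.

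Between day 2 and day 0, Clca3a1 and Clca3a2 were higher in control cells, with log2 ratios of 1.94 and 1.92, and lower in knockdown cells, at -1.18 and -1.20, differences of -3.13 and -3.12. With normexp the ratios in knockdown cells were -0.99 and -0.94, short of 2-fold. The receptor component gene Ramp2, a dim gene, had a log2 ratio of 2.33 in control cells and was not well above background in knockdown cells at day 2, so that its -1.19 there and the difference of -3.52 are bounds. With normexp its bound in knockdown cells pointed the other way and was set to 0, so the opposite direction was lost.

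Probes named by chromosome position, with no gene in the table used, were outside the comparisons. Of 16170 such probes, 7392 were at least 2-fold higher in knockdown cells at day 0, where dim signals read higher on the knockdown array, and 284 at day 2. Higher at both days were 146, where independent lists would share 129.8, and 63 were lower at both, where they would share 16.8. No bounds were applied here. The expected numbers were taken over all these probes, also those not well above background, which makes them smaller.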

How the results depend on the processing

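The bright-gene and no-detrending settings were chosen after seeing the data. Each group has 1 array, so there are no replicate pairs, and leaving out an array would empty its group. A model that pairs knockdown and control by day, with their interaction as error, could be fitted and was not, since that interaction is itself described here. With quantile normalization and cyclic loess, counts for knockdown against control at day 2 and for the knockdown time course stayed within 1.5 times of the main ones, while several counts that use the control day 0 array did not. With normexp on median signals, 1315 genes were higher and 553 lower in knockdown cells at day 0, 452 lower at day 2, 1778 higher in the control time course, and 1214 had a knockdown ratio at least 1 lower at day 2. After quantile normalization the numbers were 1095 higher and 1295 lower at day 0, 1264 higher in the control time course, and 876 higher and 1082 lower for the difference of ratios. After cyclic loess they were 980 and 1726, then 1128 higher and 2623 lower in the control time course, and 1215 higher and 921 lower for the difference of ratios. With no filter on dim probes, 5504 genes were higher at day 0, 1290 lower at day 2, 5654 higher in the control time course, and 1215 higher and 5904 lower for the difference, and the correlations were 0.16 for the knockdown ratios and 0.38 for the day ratios. The 1.5-fold size, which takes in smaller differences by construction, gave 5612 higher and 1724 lower at day 0, 1488 and 1665 at day 2, 5885 and 2712 in the control time course, 2492 and 3083 in the knockdown time course, and 1382 and 3998 for the difference. Bright genes only, fewer by construction, gave 641 and 353 at day 0, 344 and 411 at day 2, 866 and 883 in the control time course, 1051 lower in the knockdown time course and 755 lower for the difference, with correlations of 0.50 and 0.74. The Lamp2 log2 ratios stayed below 0 in each setting: the NM_010685 probe was at -0.44 with normexp and -0.52 with quantile normalization at day 0, and at -0.20 with quantile normalization and -0.19 with cyclic loess at day 2, and the NM_001017959 probe at -1.89 at day 0 and -1.88 at day 2 with normexp, and at -1.93 at day 0 without detrending. Called list medians kept their sign in the settings where at least 5 members were compared, except that of NRF2 targets for the difference of ratios, at 0.021 as the median of the probes of a gene. The bone and cartilage list, at -1.23 for the difference, was not run with bright genes only, where its 3 members had a median of 0.79. Across settings, fewer lists stayed outside the central 95% of random lists: at the lowest, 14 of 17 at day 0 and 12 of 15 in the control time course with quantile normalization, 14 of 17 at day 2 with normexp, 15 of 17 in the knockdown time course with bright genes only, and 13 of 17 for the difference with no filter on dim probes. The named genes past 2-fold kept their sign except Zfp467 in the control time course, at 0.27 as the median of the probes of a gene, Hif3a, at 1.496 in the control and 0.175 in the knockdown time course in that setting, Ramp2 in the knockdown time course, at 0 with normexp, and Myh11 at day 0, at 0 with quantile normalization and cyclic loess. The sizes of gene values often moved by more than the spot SD: with normexp 147 did and 103 did not. With quantile normalization 133 moved and 117 did not, with cyclic loess 112 and 138, and without detrending 68 and 182. Apart from the numbers fixed by construction, the cause was not tested. Dim genes, with a spot SD of 0.31 to 0.41, limit what the arrays can show.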

Other observations

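In this part, the tests on dim genes and on genes shared by both days were chosen after the results were seen. Genes of lists not described above also differed. The kinase gene Mtor was 3.63-fold higher at day 2 than at day 0 in control cells and 5.47-fold higher in knockdown cells, and the retinoic acid receptor gene Rara 2.49-fold and 3.12-fold higher. In macroautophagy, Atg12 was 3.88-fold and 3.69-fold higher at day 2 in control and knockdown cells, and the receptor gene Optn 3.60-fold and 2.36-fold lower. The oxidative stress gene Hmox1 was 3.73-fold and 4.10-fold lower at day 2, while Gclc, of glutathione synthesis, was 4.08-fold and 9.44-fold higher. The small heat shock gene Cryab was 10.2-fold and 16.9-fold lower. The chaperone-mediated autophagy list lay within the central 95% of random lists in both knockdown comparisons and above it for the difference between their log2 ratios, with a median of 0.25 at the 97.8 percentile, outside in 8 of 10 other settings.

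Between knockdown and control cells, Il1rl1, which encodes the receptor of interleukin 33, was 3.93-fold higher at day 0 and 5.55-fold higher at day 2. Lpin1, of triglyceride synthesis, was 2.03-fold and 2.72-fold higher. Cryab was 2.22-fold and 3.66-fold lower. Birc3 was 2.81-fold and 2.13-fold lower, against the direction of its list, that of NF-kB and inflammatory genes. This list had median log2 ratios of 0.50 at day 0 and 0.49 at day 2. These lay at the percentiles 99.95 and 99.97 of random lists. Of its members, 13 of 16 at day 0 and 12 of 17 at day 2 were above 0. By at least 2-fold, 1 was higher and 2 lower at day 0, and 4 were higher and 3 lower at day 2. At day 2, Irs2, of insulin signalling, was 2.27-fold higher and Lcn2 4.18-fold lower.

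Dim genes read higher on the knockdown day 0 array than on the control day 0 array. A change in expression in the cells would leave genes that fibroblasts do not express in place, but the olfactory receptor genes had a median log2 difference of 1.30, which argues against it as the whole cause. The 3 dimmest spike-in RNAs, which do not come from the cells, had a median difference of 0.85 and the 7 brighter ones -0.17. For this pair of arrays, that is what a low-signal response of the arrays would give. On the knockdown day 2 array the olfactory receptor genes also read higher than on the control day 0 array, by a median of 1.19. There the 3 dimmest spike-ins, with scaling left out, went both ways, at -0.35, 0.58 and 0.15. The spike-ins thus did not follow the dim genes on every array. Whether the slide, the hybridisation or the scan set that response stays open.

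Many bright genes differed between knockdown and control cells in the same direction at both days, among them matrix and contractile genes with differences far over 10-fold. The slide of the control day 0 array as the whole cause is argued against by the day 2 comparison, made within 1 slide: genes lower at both days were 13.1 times as many as independent lists would share. A difference between the cell populations other than the knockdown itself, such as their passage or selection, could also give differences present at both days (r = 0.50 across bright genes). With 1 population of each kind it cannot be told apart from an effect of the knockdown, and the biological explanation, the loss of LAMP2A, stays open as untested.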
